A study of Arabidopsis thaliana with 16 samples.

How the data were processed

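Whole seedlings of Col-0 and of the ein2 mutant were grown in the dark at 24 C for 3 days and treated with air or with 10 ppm ethylene for 4 hours, per the labels. ENAP1 was precipitated with an antibody against green fluorescent protein, and input samples had no antibody. The 16 samples form 8 groups of 2 replicates, 4 of ChIP and 4 of input. The labels do not say whether the replicates came from separate batches of plants. In the peak set names, the air ChIP libraries of both lines carry plain numbers. The ethylene ChIP libraries and all inputs carry numbers with the letter C. What this means is not given in the sources used here.

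Reads were aligned with BWA and peaks called with MACS2 2.1.0.20150603 on TAIR10, per the submitters' processing notes. The BWA version, filters and calling threshold are not given in the sources used here. Per the labels, both ChIP samples of a condition name the same peak file, so each condition has 1 peak set. Whether it was called on pooled reads or selected by agreement between the replicates is not given in the sources used here. The name of each set holds the word optimal and the numbers of both ChIP libraries. Set sizes and lowest q values may therefore partly reflect agreement between replicates. The deposited files give for each peak its start, end and summit offset in bp, and the fold enrichment of the ChIP signal over the local background at the summit, a ratio computed by the authors. They also give the −log10 p and −log10 q values of each peak as the authors' peak caller wrote them. The peak names in the deposited files are numbered up to 18877 in Col-0 air, 12046 in Col-0 ethylene, 8191 in ein2 air and 10236 in ein2 ethylene. The files hold 41.6%, 42.6%, 39.7% and 45.9% of these numbers, so they are subsets of longer lists. The rule of selection is not given in the sources used here. It left different lowest −log10 q values in the 4 sets, which affects every count and overlap: a set with a lower minimum holds weaker regions. Because fold and q depend on each set's own depth and background, fold was not compared between sets, apart from an alternative that applied the same fold minimum to every set, whose counts carry this limit. Of 6 peak files, 4 were used. The other 2 are named in no sample label and were not used here, nor were their columns.

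Touching or overlapping entries were to be merged into regions, but none touched, and no entry lay on an organelle chromosome. Starts are printed 1-based. Genes came from a RefSeq table of assembly TAIR10.1, whose name differs from that of the peak files, so no coordinate of the table is printed. As a check, summits were shifted by 11 offsets from −20000 to 20000 bp. In 20 of 20 combinations of set and chromosome the share of summits within 300 bp of a gene edge was highest at offset 0, at 69.1% or more, and at most 28.9% at shifts of 2000 bp or more. All 223 loci of the gene lists were found in the table. The name ENAP1 for AT3G11100 is from general knowledge, since the table pairs that locus with no symbol.

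The design fixed before the data were examined differs from what was run in these points. The table gives neither strand nor exons, so promoter, UTR, exon and intron classes, windows at gene starts and placement by distance to gene starts were not run. A gene instead means its span with 1000 bp on both sides, and summits were classed as inside a gene, within 1000 bp or farther. Motif analysis was not run because no genome sequence was used here. A list of cytosolic ribosomal protein genes was not built, because symbols alone do not separate them from other genes. Of the 18 lists tested, 17 were written out beforehand, and the histone genes were found from gene symbols, as planned.

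Regions were counted as shared if they overlapped by at least 1 bp. Shares were set against 1000 random placements of the same regions on the same chromosome. Placement at the same distance from an edge of a randomly drawn gene was added after seeing the data. The number of list members with a region was set against 10000 random lists of the same size matched on 10 classes of gene length, and is given as a percentile, with ties counted at their middle. These are descriptions of single sets, not tests between conditions. Genes were named by a fixed rule: for each of 4 comparisons, the genes of the 5 regions of highest fold in the first set alone, the 5 in the second alone and the 5 shared, with the ENAP1 locus and any member of the lists in addition. The gene of a region was the one that held its summit or was nearest within 1000 bp, by gene edge instead of gene start. The block on chromosome 2, the regions compared at EIN2, the gene families and the genes of the widest regions were singled out after seeing the data, and the share of ein2 ethylene regions without an ein2 air counterpart that lie in Col-0 air was added then too.

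Alternatives listed beforehand were a −log10 q of at least 5, entries unmerged, organelle chromosomes included, circular shifts, flanks of 500 and 2000 bp, overlap of 50% of the shorter region, summits within 200 bp, summits for gene calls, unmatched lists, and equal numbers of regions by −log10 p, as many as the smaller set of a pair holds for overlaps and as many as the smallest of the 4 sets holds elsewhere. Alternatives added later were a common −log10 q minimum, a fold of at least 3, removal of the block, placement by gene edge and 1 nearest gene per region. Confidence intervals are Wilson intervals from scipy 1.17.1, in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The overlap and list procedures were tested on simulated data. Planted overlap shares in 6 simulated cases with the widths of the Col-0 and ein2 sets were found within 0.0782 percentage points. Of 400 random lists of 16 drawn from 27444 genes with no excess in Col-0 air, 3.50% were in the highest 2.5% of random lists, and of 400 lists with planted excess, 72.0% were.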

Results

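Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map ENAP1 in Arabidopsis thaliana. ENAP1 is a nuclear protein that interacts with EIN2, the membrane protein through which ethylene perception is passed to the nucleus. An antibody against green fluorescent protein was used on whole seedlings grown in the dark for 3 days and then kept for 4 hours in air or in air with 10 ppm ethylene. The lines were Col-0, the wild-type reference accession, and ein2, a mutant that does not respond to ethylene. Each of the 4 conditions had 2 ChIP and 2 input samples, 16 in all. No sample is a ChIP from plants without tagged ENAP1. Signal that the antibody gives without ENAP1 can therefore not be told apart from binding. The labels name 1 peak set for both replicates of a condition. No replicate spread can therefore be given for any value, and no difference between conditions was tested. The deposited peak files hold no read counts, so library depth is unknown. In both lines the air and ethylene ChIP libraries are also numbered in different ways. If this marks separate handling, its effect cannot be told apart from that of ethylene. Positions refer to TAIR10 as given in the peak files. Fold enrichment is the authors' own value per peak and is used to describe and rank regions within their own set. Intervals are Wilson 95% intervals and cover counting error only.

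A region lay at the ENAP1 gene itself (AT3G11100) in all 4 sets. Since the antibody is against a tag, DNA of a tagged ENAP1 copy could also give reads at this gene, which was not tested. Its summit fell inside the gene, at position 3477448 of chromosome 3 in Col-0 air, with a fold of 6.78, and 11.5% of the regions of that set had a higher fold. Within their own sets, 10.2% of the regions had a higher fold than the ENAP1 region in Col-0 ethylene, 46.5% in ein2 air and 68.3% in ein2 ethylene. The strongest region of Col-0 air, with a fold of 19.9, spanned 15999772 to 16000136 of chromosome 2 in APD1 (AT2G38185), and an overlapping region led the ein2 air set with a fold of 13.7. The strongest region of Col-0 ethylene lay in AT3G28335. Col-0 air had 7852 regions, Col-0 ethylene 5137, ein2 air 3252 and ein2 ethylene 4696. They covered from 1.05 Mb in ein2 air to 2.87 Mb in Col-0 air, with median widths of 323, 322, 290 and 279 bp. The lowest −log10 q that the authors kept differed between the sets, at 13.4 in Col-0 air, 10.8 in Col-0 ethylene, 10.9 in ein2 air and 6.57 in ein2 ethylene. With the highest of these minima applied to every set, the 4 sets held 7852, 4177, 2689 and 1949 regions, so that ein2 ethylene went from above to below ein2 air.

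ENAP1 regions were found at genes, and close to gene ends in particular. The summit lay inside a protein-coding gene for 70.3% of the Col-0 air regions (interval 69.3 to 71.3), 74.4% in Col-0 ethylene (73.2 to 75.6), 78.8% in ein2 air (77.4 to 80.2) and 68.3% in ein2 ethylene (67.0 to 69.6). Random placement of the same regions gave 54.2% on average in each set and at most 57.6%. Within 300 bp of an edge of a protein-coding gene lay 71.3%, 73.0%, 75.7% and 71.9% of the summits, against at most 26.0% in random placements and circular shifts. The 100 bp just inside a gene edge alone held 27.8%, 27.9%, 30.4% and 28.1% of the summits. Regions over 1000 bp from any protein-coding gene were few, at 6.33%, 4.19%, 4.00% and 6.94%, where random placement gave 25.3% to 25.4%. Annotated pseudogenes held 0.624%, 1.30%, 0.646% and 0.468% of the summits, against 8.71% to 8.77% at random. The gene table used gives no strand, so the start and the end of a gene are not told apart here.

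**Figure D1:**
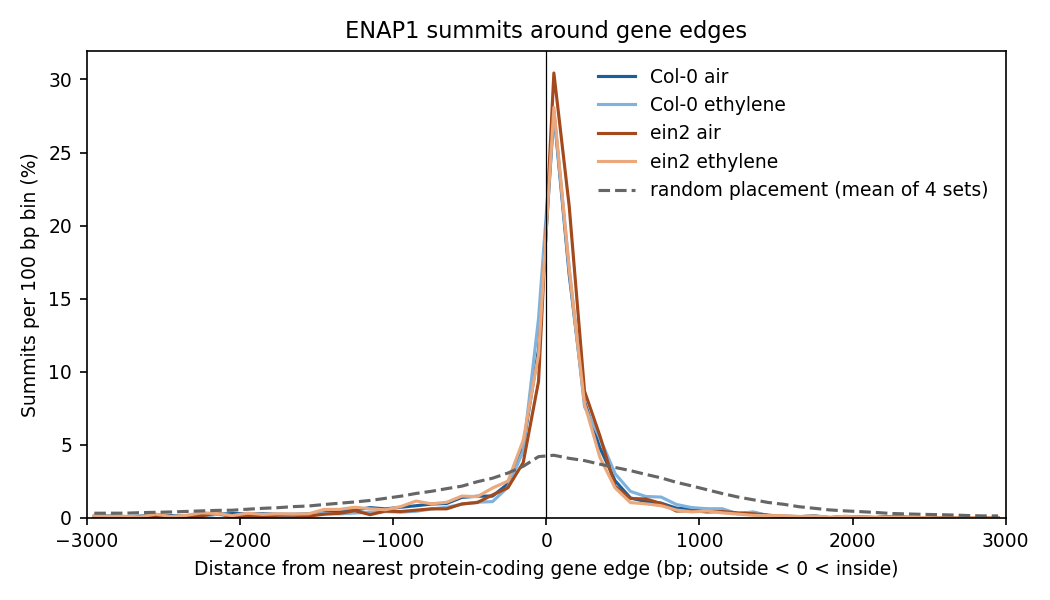
Share of ENAP1 summits (percent per 100 bp bin, y axis) by signed distance to the nearest protein-coding gene edge (bp, x axis, positive inside the gene), 1 line per condition, with the mean of random placements dashed. All 4 sets peak in the bin just inside the edge, at 27.8% to 30.4%, where random placement gives 4.20% to 4.34%.

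Ethylene was compared with air in Col-0 to ask where ENAP1 occupancy differs after 4 hours of the hormone. Of 16 ethylene signalling genes, 12 had a region in Col-0 air, and 6 of these had one in Col-0 ethylene, namely the receptors ETR1 and ETR2, EIN2, the transcription factor EIN3, the exonuclease EIN5 and the F-box gene ETP2. The receptors ERS1, ERS2 and EIN4, the kinase CTR1, EIL1 and the F-box gene EBF1 had a region in air and none in ethylene. Of all genes with a region in Col-0 air, 66.7% had one in Col-0 ethylene. In a check added after seeing the data, random lists of 12 such genes kept 7.99 on average. As few as 6 were kept by 17.6% of these lists, and by 3.38% of lists matched on Col-0 air fold. Among 19 ethylene-induced genes, 8 had a region in air and 1 of them, ETR2, also in ethylene, while EDF1, EDF3, EDF4, ARL, ARGOS, ERS1 and ERS2 did not. The jasmonate genes JAZ1, JAZ2, JAZ3, JAZ6, JAZ9, JAZ12, MYC2 and AOS, 8 in all, had a region in both conditions. The cellulose synthase genes CESA1, CESA3 and CESA6 and the xyloglucan enzyme gene XTH4 had a region in air, and none of the 8 cell wall genes had one in ethylene.

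Of the Col-0 air regions, 58.2% overlapped a Col-0 ethylene region (interval 57.1 to 59.3), and 88.2% of the Col-0 ethylene regions overlapped a Col-0 air region (87.3 to 89.1). Random placement reached at most 5.94%, and placement at the same distance from edges of other genes at most 13.3%. In the decile of Col-0 air regions with the highest fold, 93.3% were also found in ethylene. The strongest regions found in air without an overlapping ethylene region lay in or near VEL1 (AT4G30200), a relative of the vernalization gene VIN3 (chromosome 4, 14790202 to 14790638, fold 11.6), the transcription factor genes LBD38 (AT3G49940) and MYB70 (AT2G23290), RTFL8 (AT2G39705), and FZR2 (AT4G22910), which encodes an activator of the anaphase-promoting complex. LBD38 had another region in Col-0 ethylene. The strongest regions found in ethylene without an overlapping air region lay near AT2G18110, in RUP1 (AT5G52250), a repressor of UV-B responses (chromosome 5, 21217436 to 21218099, fold 4.92), in AT2G36240, in EIN3 (AT3G20770) and in AT3G20800. The EIN3 region spanned 7260713 to 7262634 of chromosome 3, 1922 bp, with a fold of 4.86, whereas the Col-0 air region at the same gene spanned 7263153 to 7263341. Shared regions of highest fold lay in or near APD1, AT5G38220, RABC2A, RAD9 and AT5G02220, a cyclin-dependent kinase inhibitor gene also called SMR4. At the gene level, 6501 of 9747 genes with a region in air had one in ethylene, and 695 genes had one in ethylene and not in air. With the 5137 regions of lowest p from each set, 76.1% of the Col-0 air regions and 75.9% of the Col-0 ethylene regions were shared.

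The same comparison in ein2 is the control in which EIN2-dependent signalling is absent. Of the 16 ethylene signalling genes, ETR1, ETR2, EIN2 and EIN5 had a region in both ein2 sets. ERS1, EIN3, EIL1 and EBF1 had a region in ein2 ethylene and not in ein2 air, and EIN4 and ETP2 the other way round. The ethylene-induced genes ARL and ETR2 had a region in both, and ERF1, EDF1, EDF3, ARGOS and ERS1 had one in ein2 ethylene without one in ein2 air. The auxin genes TAA1, AUX1, IAA1, IAA29 and ARF2 were likewise found in ein2 ethylene and not in ein2 air. Apart from ERF1 and IAA1, all of the genes named here with this pattern also had a region in Col-0 air. In all, 2219 genes showed it, and ein2 ethylene was kept down to a −log10 q of 6.57, against 10.9 in ein2 air. All 6 housekeeping genes with a region in ein2 air, among them ACT2, ACT8 and UBQ10, kept one in ein2 ethylene.

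In ein2, 82.4% of the air regions were found in ethylene (interval 81.0 to 83.7) and 57.3% of the ethylene regions in air (55.8 to 58.7), against at most 7.84% in random placements of either kind. The strongest regions of ein2 air without an ethylene counterpart lay in MPK2 (AT1G59580), XBAT33 (AT5G07270), KELP (AT4G10920) and AT2G20400 and near the ubiquitin ligase gene PUB22 (AT3G52450), with folds of 5.66, 5.54, 5.33, 4.92 and 4.77. Those of ein2 ethylene without an air counterpart lay near HEC2 (AT3G50330), in GLIP5 (AT1G53920), and near ICE1 (AT3G26744), a regulator of the cold response, CDF3 (AT3G47500) and AT4G13710. All 5 of these genes had a region in Col-0 air as well. Shared regions of highest fold lay in or near APD1, AT5G38220, AT5G02220, AT1G11200 and PRA1.F4 (AT3G13710), a prenylated Rab acceptor gene. At the gene level, 3932 of the 4633 genes with a region in ein2 air had one in ein2 ethylene, and 2219 had one in ethylene and not in air. With the 3252 regions of lowest p from each set, 71.1% of the ein2 air regions and 71.2% of the ein2 ethylene regions were shared. At the common −log10 q minimum the order was the other way round, with 57.8% of the ein2 air regions found in ethylene and 79.7% of the ein2 ethylene regions in air.

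Col-0 and ein2 were compared in air to ask whether loss of EIN2 alters ENAP1 occupancy without added ethylene. None of the 11 gibberellin genes had a region in ein2 air, while the growth repressor genes RGA, RGL1, RGL2 and RGL3 and the receptor genes GID1A and GID1B had one in Col-0 air. Of the ethylene biosynthesis genes, ACS2, ACS5, ACO4, ETO1 and EOL2 had a region in Col-0 air, and 0 of 16 had one in ein2 air (Wilson upper bound 19.4%). The signalling genes ETR1, ETR2, EIN4, EIN2, EIN5 and ETP2 had a region in both lines, whereas ERS1, ERS2, CTR1, EIN3, EIL1 and EBF1 had one in Col-0. Among random lists matched on gene length, the 0 of 11 gibberellin genes in ein2 air is at percentile 5.1, with a random mean of 2.05. The 0 of 16 biosynthesis genes is at percentile 1.60, with a mean of 3.03. Nearly every gene with a region in ein2 air, 4577 of 4633, had one in Col-0 air. In the other direction, 47.0% of the 9747 genes with a region in Col-0 air had one in ein2 air, the smaller set.

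Of the ein2 air regions, 98.4% overlapped a Col-0 air region (interval 97.9 to 98.8), and 40.6% of the Col-0 air regions overlapped an ein2 air region (39.5 to 41.7). Random placements of either kind reached at most 13.1%. These shares depend on set size. With the 3252 regions of lowest p from each set, 78.7% of the Col-0 air and 79.3% of the ein2 air regions were shared. Among the Col-0 air regions, 7.51% of those in the lowest decile by fold and 96.4% of those in the highest decile overlapped an ein2 air region. The strongest Col-0 air regions without an ein2 air counterpart lay in COP8 (AT5G42970), a subunit of the COP9 signalosome, and near AGL19 (AT4G22950), AT1G60010, AT2G28620 and CDF3, with folds of 9.59, 9.43, 9.30, 9.14 and 8.72. All 5 of these genes had a region in ein2 ethylene. The strongest ein2 air regions without a Col-0 air counterpart lay in SUE4 (AT3G55880), the cyclin-dependent kinase inhibitor gene ICK1 (AT2G23430), AT4G17505, SIP1 (AT5G58380), a CBL-interacting protein kinase gene, and VRN1 (AT3G18990). Their folds were 4.69, 4.55, 4.36, 4.31 and 4.23. The genes SUE4 and ICK1 had another region in Col-0 air.

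In ethylene, the lines were compared to ask whether EIN2 affects where ENAP1 lies after the hormone is given. ETR2 was the 1 ethylene-induced gene with a region in both lines, and ERF1, EDF1, EDF3, ARL, ARGOS and ERS1 had a region in ein2 and not in Col-0. ETR1, ETR2, EIN2, EIN3 and EIN5 had a region in both lines, ETP2 in Col-0, and ERS1, EIL1 and EBF1 in ein2. Among 14 histone acetylation genes, the acetyltransferase genes GCN5, HAG2, HAM1, HAM2 and HAF1 had a region in both, HAC1, HAC5 and the deacetylase gene HDA19 in Col-0, and the deacetylase gene HDA9 in ein2.

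Of the Col-0 ethylene regions, 57.3% were found in ein2 ethylene (interval 55.9 to 58.6), and 63.2% of the ein2 ethylene regions in Col-0 ethylene (61.8 to 64.5), against at most 9.16% in random placements of either kind. At the common −log10 q minimum the Col-0 ethylene share was 37.4% and the ein2 ethylene share 80.1%. The strongest Col-0 ethylene region without an ein2 ethylene counterpart lay in EIN2 itself (AT5G03280), at 790953 to 793141 of chromosome 5, with a fold of 8.96 and a width of 2189 bp. In Col-0 air, regions at 791040 to 792596 and 792694 to 793073 lay in the same stretch, and in ein2 air a region at 792739 to 793052. A further region just outside the EIN2 gene, with its summit at 793650 in Col-0 ethylene and 793663 in ein2 ethylene, was present in all 4 sets. The next in fold lay near AT2G25760, in PGIP1 (AT5G06860), which encodes an inhibitor of fungal polygalacturonases, in AT5G62560 and near AT1G07615. AT5G62560 had another region in ein2 ethylene. The strongest ein2 ethylene regions without a Col-0 ethylene counterpart lay in VEL1, the glutamate decarboxylase gene GAD (AT5G17330), ACT2 (AT3G18780) and TBL38 (AT1G29050) and near HEC2. All of these had a region in Col-0 air too. Shared regions of highest fold lay in AT3G28335, AT2G31590, AT5G11550 and AT2G46520 and near FRS2 (AT2G32250). At the gene level, 4496 genes had a region in both lines, 2700 in Col-0 and not ein2, and 1655 in ein2 and not Col-0.

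Across both lines, the ethylene difference had a different sign in the number of regions. Col-0 ethylene had 605 regions that overlapped no Col-0 air region, and 3285 Col-0 air regions overlapped no Col-0 ethylene region. In ein2 these numbers were 2007 and 573. At the common −log10 q minimum they were 395 and 1135 in ein2, so that the sign there was the same as in Col-0, and 295 regions were found in Col-0 ethylene and not air. With a fold of at least 3 in every set, ein2 ethylene minus ein2 air was -1101 regions. RUP1 and the light-harvesting gene LHCB4.1 had a region in Col-0 ethylene alone among the 4 sets, as did the gibberellin biosynthesis gene GA20OX2 and the clock genes PRR5 and PRR9. Of the 605 regions, 63 (10.4%, interval 8.22 to 13.1) overlapped an ein2 ethylene region. For 57 (9.42% of the 605) it was one without an ein2 air counterpart, a share that became 0% at the common −log10 q minimum. By definition the 605 regions overlap no Col-0 air region, whereas most ein2 ethylene regions without an ein2 air counterpart do. A low share was thus partly fixed in advance, and no random level is given for it. Of the 2007 ein2 ethylene regions without an ein2 air counterpart, 1404 (70.0%, interval 67.9 to 71.9) overlapped a Col-0 air region. Those at HEC2, GLIP5, ICE1, CDF3 and AT4G13710 are among them. At equal numbers of regions, 3252 from each of the 4 sets, gains and losses are nearly even by construction: the Col-0 numbers were 729 and 731 and the ein2 numbers 938 and 940, and the overlap with Col-0 air was 23.7%. Over the union of 8965 regions, 2269 (25.3%) belonged to all 4 sets, 1995 to Col-0 air alone, 545 to ein2 ethylene alone, 539 to Col-0 ethylene alone and 24 to ein2 air alone.

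**Figure D2:**
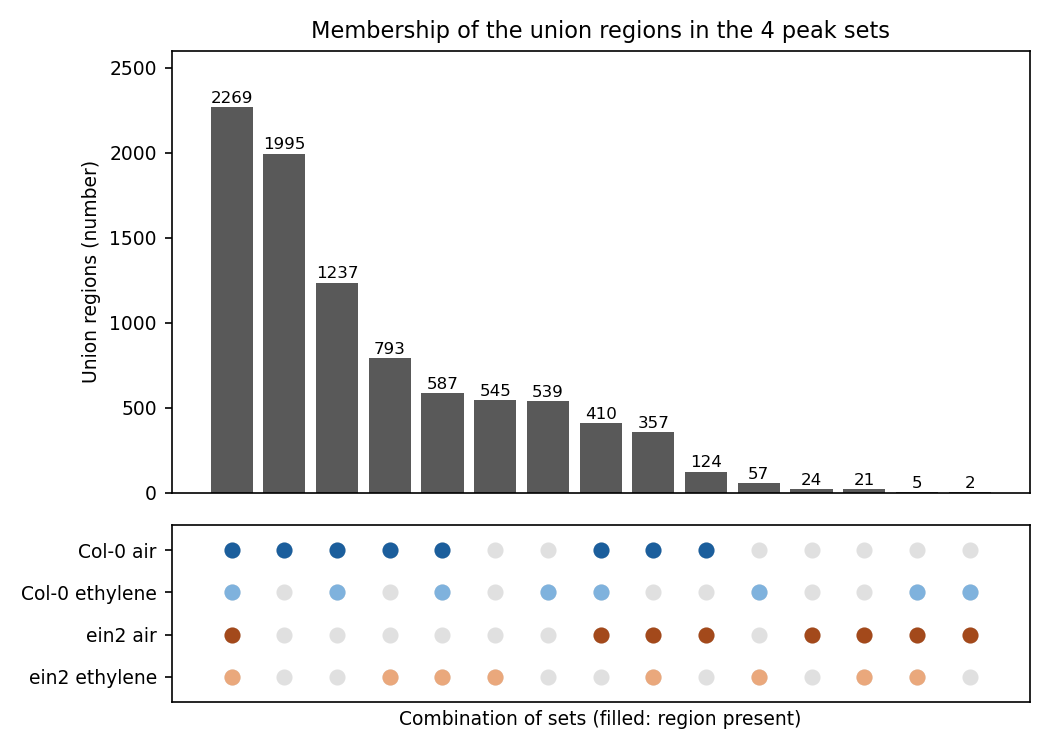
Number of union regions (y axis) for each combination of the 4 peak sets, with filled circles marking the sets that contain the region. The combination of all 4 sets is the most frequent with 2269 regions, followed by Col-0 air alone with 1995 and both Col-0 sets with 1237.

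Ethylene response factor genes stood out among 18 gene groups. Of 19 ERF family genes, 15 had a region in Col-0 air, 9 in Col-0 ethylene, 7 in ein2 air and 9 in ein2 ethylene, which are percentiles 100, 99.2, 99.4 and 99.8 among random lists matched on gene length. ERF4, ERF5, ERF6 and ERF9 had a region in every set, and RAP2.12, which responds to low oxygen, in all but ein2 air. At 3252 regions from each set (equal numbers), the percentile was 97.4 in Col-0 air and 83.4 in ein2 ethylene, and with unmatched lists it was 97.3 in Col-0 ethylene. Brassinosteroid genes had a region at 6 of 7 in Col-0 air and in ein2 ethylene, percentiles 98.3 and 99.9, and at 3 in Col-0 ethylene and 4 in ein2 air, with BRI1, the brassinosteroid receptor gene, and CPD and BAS1 in every set. Their Col-0 air percentile was 97.0 at equal numbers. The jasmonate genes had 8 of 13 with a region in Col-0 air, 5 in ein2 air, and 8 in Col-0 ethylene and in ein2 ethylene, the ethylene sets at percentiles 99.1 and 99.8, which became 83.8 and 95.3 at equal numbers. Ethylene signalling genes were at the 99.4th percentile in Col-0 air with 12 of 16, and at 72.7, 94.0 and 97.0 in the other sets with 6, 6 and 8. Histone acetylation genes had 10 of 14 in Col-0 air, percentile 97.8, and 95.3 at equal numbers, and 8, 5 and 6 in the other sets. Housekeeping genes had 7 of 10 in Col-0 air, 4 in Col-0 ethylene and 6 in both ein2 sets, the last at percentiles 99.7 and 98.8.

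Flower identity genes, which are used in another tissue, had no region in any set. The 0 of 10 members, among them AP1, AG, LFY and SEP3, are at percentiles 0.185, 1.05, 4.87 and 2.00 in Col-0 air, Col-0 ethylene, ein2 air and ein2 ethylene, and at equal numbers the values in Col-0 air, Col-0 ethylene and ein2 ethylene became 4.41, 4.62 and 5.01. Seed storage genes, also of another tissue, had 4 of 8 in Col-0 air and 2 of 8 in each other set. Ethylene-induced genes had 8, 1, 2 and 7 of 19, and the 1 in Col-0 ethylene is at percentile 1.43, or 7.31 at equal numbers and 8.48 with each region given to its nearest gene. Ethylene biosynthesis genes had 5, 1, 0 and 2 of 16, with 1.56 in Col-0 ethylene and 1.60 in ein2 air, or 7.81 and 5.61 with the nearest gene. Cell wall growth genes had 4, 0, 2 and 4 of 8, with 2.71 in Col-0 ethylene, and histone genes 10, 7, 3 and 5 of 21, with 97.7 in Col-0 air and 79.4 at equal numbers. Outside the highest and the lowest 2.5% of random lists in every set were the auxin genes with 10, 5, 2 and 7 of 18, the gibberellin genes with 6, 4, 0 and 3 of 11, and the clock genes, TOC1 and GI among them, with 6, 6, 3 and 5 of 10. The same held for dark and light growth regulators such as HY5 and PIF5 with 7, 6, 2 and 4 of 14, light harvesting genes with 3, 4, 1 and 2 of 11, and heat shock genes with 1, 2, 0 and 0 of 8. In all, 10899 of 27444 protein-coding genes had a region in some set and 3517 in every set. By set the numbers were 9747 (35.5%), 7196 (26.2%), 4633 (16.9%) and 6151 (22.4%). With each region given to 1 gene they were 4665 in Col-0 ethylene and 3020 in ein2 air.

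**Figure D3:**
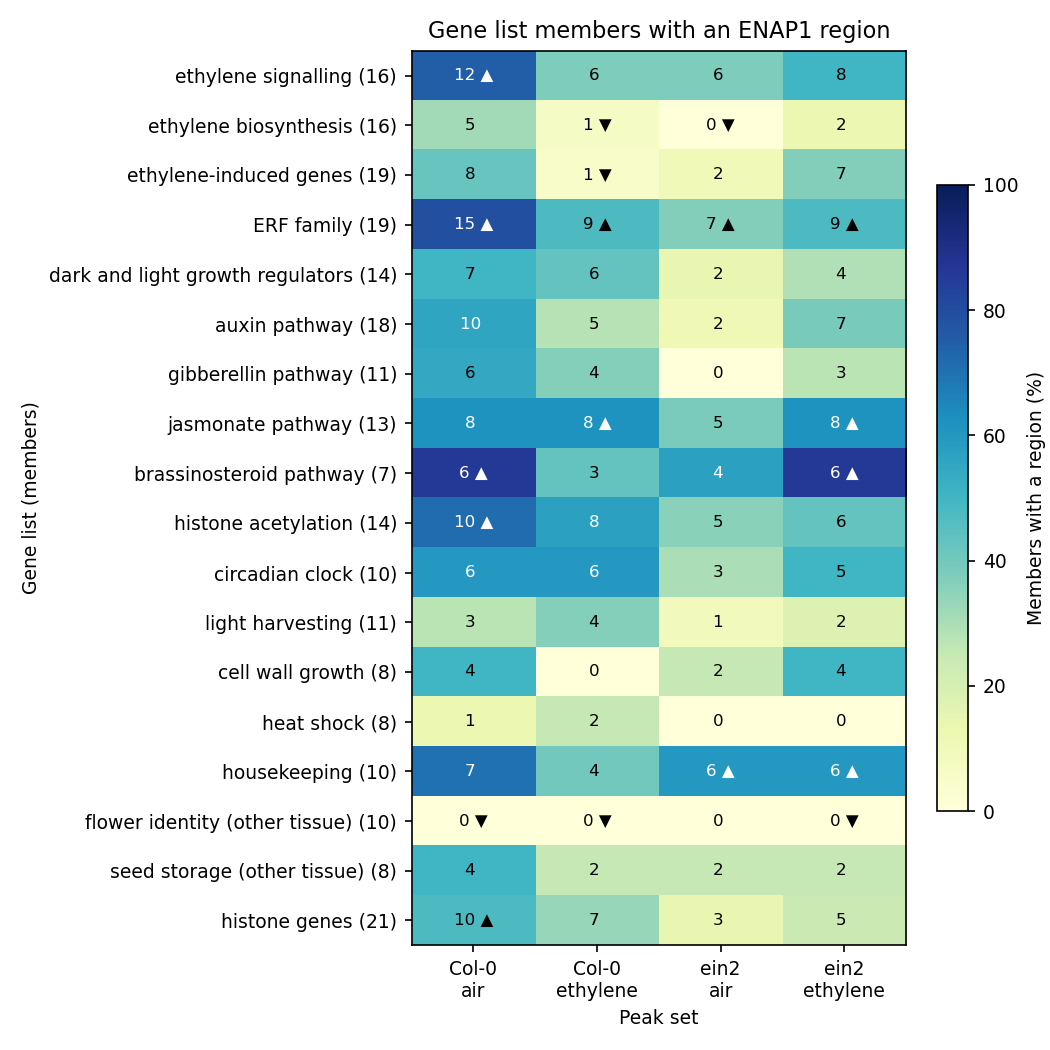
Gene lists (y axis, number of members in brackets) against the 4 peak sets (x axis). Cell colour is the percent of members with a region, the number is the count of such members, and triangles mark counts in the highest 2.5% (up) or lowest 2.5% (down) of random lists matched on gene length. ERF family genes have an upward triangle in all 4 sets, with 15, 9, 7 and 9 members.

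On chromosome 2, Col-0 ethylene had a block of wide regions side by side between 3253599 and 3502173. The block held 36 regions that covered 219 kb, 88.1% of the block and 10.4% of all base pairs covered in that set. Their fold ranged from 1.65 to 1.80, against a median of 3.77 for the rest of the set. Of these regions, 25 were wider than 2500 bp, and 1 region of that width lay elsewhere in the set. The limits of the block are those of its regions of that width, and 5 narrower Col-0 ethylene regions with folds of 1.68 to 1.80 lay within 100 kb outside them. Col-0 air had 1 region in the block, over 0.110% of its length, and the ein2 sets had 0.

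**Figure D4:**
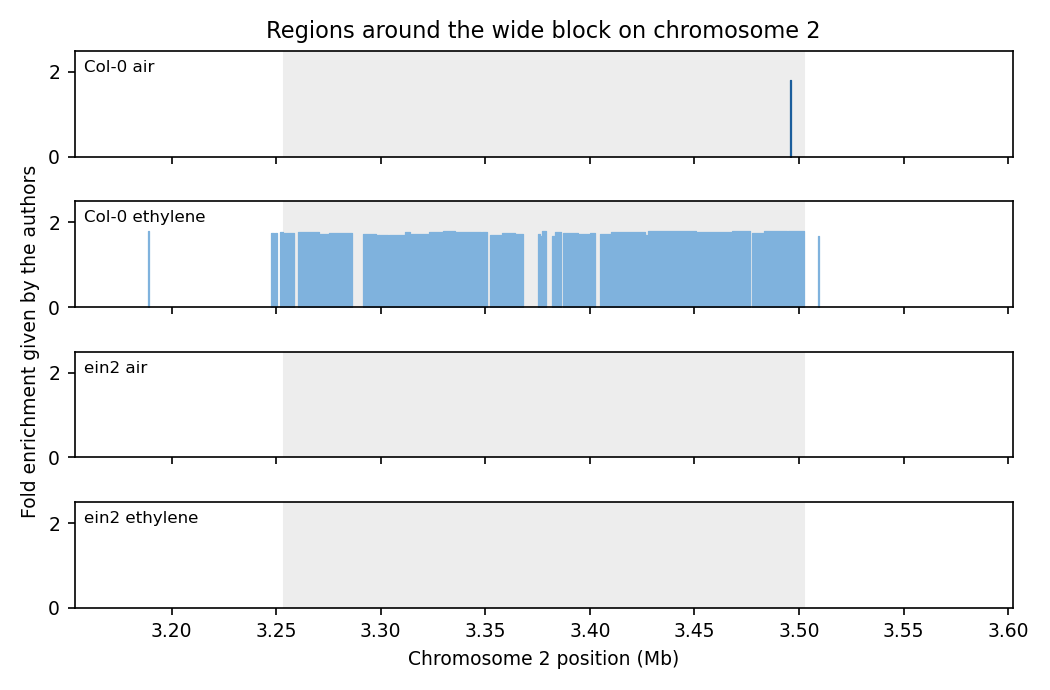
Regions around the block on chromosome 2 (x axis, position in Mb), 1 panel per condition, drawn as bars from start to end with the authors' fold enrichment as height (y axis) and the block shaded. The Col-0 ethylene panel holds the 36 regions of the block at folds of 1.65 to 1.80, and the ein2 panels hold none.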

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

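The tests in this part were chosen after the result was seen, while the alternative with equal numbers of regions per set was listed beforehand.

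The number of regions moved in opposite directions with ethylene in the 2 lines, a difference between groups. Ethylene minus air was -2715 regions in Col-0 and 1444 in ein2, and the difference between the lines was not tested, since each condition has 1 set. A candidate explanation is that the sets were kept down to different q values: at a common −log10 q minimum the ein2 difference was -740, so the rise in ein2 is not kept there. Another is that sites called elsewhere fell under the threshold in ein2 air. Of the ein2 ethylene regions without an ein2 air counterpart, 70.0% were found in Col-0 air, against at most 11.9% in random placements at gene edges. The share was 23.7% with equal numbers of regions per set and 94.2% at the common minimum. It cannot decide between explanations, since sites added by ethylene in ein2 could also lie where Col-0 air has regions. That ethylene adds ENAP1 sites in ein2 stays open. Of the ein2 ethylene regions without an ein2 air counterpart, 73.5% (interval 71.5 to 75.4) lay under the lowest −log10 q of ein2 air. The remaining ones did not, and with 1 set per condition and unknown depth they cannot be told apart from a difference between libraries.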

How the results depend on the processing

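The common −log10 q minimum, the fold minimum, removal of the block, placement at gene edges and the nearest-gene rule were chosen after seeing the data. All 8 overlap shares stayed above every random placement under every alternative, between 33.9% and 99.2% against at most 13.3%, and so did the shares of summits near genes and gene edges. A −log10 q of at least 5, unmerged entries and organelle chromosomes removed or added no region, so these say nothing about stability. Removal of the block left in 5 regions of similar fold within 100 kb of it. Of 6 alternatives for region counts, the common minimum left 1949 and a fold of at least 3 left 1462 regions in ein2 ethylene, and ethylene minus air in ein2 reversed to -740 and -1101. In Col-0 it kept its sign under all 6, but most of these could not have reversed it. The common minimum is that of Col-0 air itself, so it removed no Col-0 air region. The block held 1 Col-0 air and 36 Col-0 ethylene regions. Only the fold minimum could have reversed the sign, and the Col-0 difference there was -3032. At the common minimum, 295 regions were found in Col-0 ethylene and not air, 395 in ein2 ethylene and not air, and 1135 in ein2 air and not ethylene. The share of Col-0 ethylene-only regions that were also ein2 ethylene-only became 0%. This was partly fixed in advance, since Col-0 ethylene-only regions overlap no Col-0 air region by definition. The share of ein2 ethylene-only regions in Col-0 air became 94.2%. With 3252 regions from each set, 731 Col-0 air, 729 Col-0 ethylene, 938 ein2 ethylene and 940 ein2 air regions lacked a counterpart in the other treatment, and that last share became 23.7%. Fewer regions by construction account for part of these moves. With summits within 200 bp it was 67.2%. With 1 nearest gene per region, 4665 genes in Col-0 ethylene and 3020 in ein2 air had a region, fewer by construction. The number of lists in the highest 2.5% of random lists became 1 in Col-0 air, 1 in Col-0 ethylene and 2 in ein2 ethylene at equal numbers. The number in the lowest 2.5% became 0 in Col-0 air and 1 in Col-0 ethylene at equal numbers, 2 in Col-0 air and 0 in the other sets with the nearest gene, and 0 in both ein2 sets with unmatched lists. The cause was not tested for the list counts and the 67.2%. Over all lists and sets, 183 percentiles stayed on their side of these limits, but most of them lay between the limits from the start. Only a percentile beyond a limit could become weaker. In the main setting 5, 2, 2 and 4 lists were in the highest 2.5% and 1, 3, 1 and 1 in the lowest. Over the alternatives 22 lost such a place, 11 of them at equal numbers, and 11 gained one. None crossed from the highest to the lowest 2.5%. For the named and list genes, the sets with a region stayed the same in 1186 cases and changed in 159. At equal numbers of regions, 81 changed and 188 stayed the same, whereas from 6 to 29 changed under each other alternative.

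No paired analysis was possible because each condition has 1 peak set for both replicates, although the labels share replicate numbers. Leaving out a replicate was not possible for the same reason. Not run were gene-start windows, placement by gene start and the motif alternatives, for want of strand and sequence. Unknown depth limits every comparison of presence and absence: a region missing from a set is not shown to be unoccupied.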

Other observations

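The gene families, the widest regions, the block on chromosome 2 and the loss of regions at ethylene-induced genes were examined only after the results were seen, and so were all tests in this part.

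Among 86 families of at least 15 genes formed from gene symbols, cytochrome P450 genes had few ENAP1 regions. Of 224 genes with P450 names, 49 had a region in Col-0 air, 42 in Col-0 ethylene, 23 in ein2 air and 35 in ein2 ethylene, where random lists matched on length gave means of 86.5, 64.5, 41.5 and 54.2. Genes with CRK symbols, used for cysteine-rich receptor-like kinases and some other kinases, had 7, 4, 2 and 1 of 40, and the glutathione transferase genes with GSTU symbols 1, 1, 0 and 1 of 27. Prenylated Rab acceptor genes (PRA), whose products act in membrane traffic, had 12, 12, 8 and 8 of 18, at percentiles from 99.5 to 100 over the sets, and genes with ERF symbols had 15, 10, 7 and 9 of 25. These 5 families were in the highest or lowest 2.5% of random lists in all 4 sets, 3 of them low and 2 high. Members of such families often lie side by side, so they are not independent. Expression was not matched here either.

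Outside the block on chromosome 2, LRX3 was among the widest regions of every set. LRX3 (AT4G13340), a leucine-rich repeat extensin gene of the cell wall, held the widest region of ein2 air, 2042 bp, and of ein2 ethylene, 1655 bp, and regions of 2152 bp in Col-0 air and 2321 bp in Col-0 ethylene. AT4G18670 held the widest in both Col-0 sets, 2517 and 2568 bp. GATA1 (AT3G24050) was among the 10 widest in Col-0 air and both ein2 sets, and AT3G54363 in Col-0 air and ein2 air. EIN2 and EIN3 came next after SIP1 (AT5G40390) and LRX3 in Col-0 ethylene, with 2189 and 1922 bp, where the median is 322 bp, and an EIN2 region of 1557 bp was 9 in order of width in Col-0 air. The regions at EIN3 in Col-0 air and ein2 ethylene were 189 and 204 bp wide.

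Regions at ethylene-induced genes were mostly missing from Col-0 ethylene. Of 8 such genes with a region in Col-0 air, 1 kept one, against a mean of 5.32 in random lists of genes with a Col-0 air region, the lowest percentile (0.140) of 13 lists examined. The tables argue against regions of low fold dropping out first, since 0.120% of random lists matched on Col-0 air fold kept as few. The lists were not matched on −log10 q, and fold orders retention poorly among weaker regions. In fold decile 1 of Col-0 air 52.5% were shared with Col-0 ethylene, and in decile 3 42.2%. That regions near the threshold in q dropped out first is therefore left open. With equal numbers of regions in both sets (1 of 6 kept), 0.130% of random lists kept as few. This argues against the smaller number of Col-0 ethylene regions as the reason. At the common −log10 q minimum 1.27% kept as few. That value does not bear on set size, since Col-0 air then held 7852 regions and Col-0 ethylene 4177. None of these percentages allows for the choice of the lowest of 13 lists. A hypothesis left open is that ethylene removes ENAP1 from such genes through EIN2: 2 of the 19 genes had a region in ein2 air and both kept it, which is too few to compare. A single set per condition and the unknown depth leave a difference between the libraries of the conditions open as well.

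The block of wide regions on chromosome 2 in Col-0 ethylene has no explanation that was borne out. Binding at gene edges, as elsewhere in the set, was argued against by the summits: 25% lay within 300 bp of a gene edge, against a mean of 33.2% for random positions in the block and at least 47.2% in the other runs. A copy of mitochondrial DNA is known near the centromere of this chromosome, but the test on gene lengths left it open, with 11.1% of mitochondrial gene lengths found in the block and up to 16.7% in random runs of genes. A different amount of this stretch of DNA in ChIP and input stays open too: the highest fold was 1.09 times the lowest, but all regions of the block lie near the lowest fold of the set, where this ratio cannot be large, so it decides nothing. Binding spread evenly over the stretch was not tested.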
